A study of Homo sapiens with 10 samples.

How the data were processed

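Total RNA of A549 and H441, which are human lung adenocarcinoma cell lines, was measured on 10 single-colour Agilent expression arrays with 60901 non-control features each. Per the labels, cells were trypsinized and placed on ultra-low attachment plates for 1 or 7 days (detached) or grown in standard culture (attached). An FL subline of each line had been kept on ultra-low attachment plates for more than 2 months and was measured both detached and in standard culture. This gives 5 culture states in each of 2 lines, 4 cell populations (parental A549, parental H441, A549-FL and H441-FL) and 10 groups of 1 array, with 6 detached and 4 attached arrays. The description field of the FL attached samples calls them detached, while their title, source and treatment fields call them attached. They were used as attached, since 3 fields name that state. RNA was isolated with RNeasy Mini columns and labelled with Cy3 by oligo(dT)-primed low input amplification, per the labels.

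The authors scanned the arrays and extracted the signals with Agilent Feature Extraction, version 12.1.0.3 per the file headers. The values used here are the deposited background-subtracted Cy3 signal intensity per feature (gProcessedSignal), on a linear scale in arbitrary units. The deposited value table holds the same intensity multiplied by 1 constant per array, between 1.76 and 2.19 on the log2 scale, and the basis of that constant is not given in the sources used here. No feature was saturated on any array. The percentage of features well above background, by the software's own call, lay between 49.8 and 53.8 per array, and the 75th percentile of the signal lay between 213 and 290. Probes spotted 10 times had a median SD between 0.055 and 0.063 on the log2 scale within an array. The spike-in detection limit was out of range on 1 array (A549 detached day 1). The arrays came from 2 slides, and the 2 FL attached arrays were the ones on slide 2, so slide and that state are confounded.

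Signals of repeated probes were averaged on the log2 scale to 58201 distinct probes, and 16 probes were dropped for an outlier call. Probes took the gene symbol whose RefSeq accession, without its version, matched the accession of the probe in a table of gene names from assembly GRCh38.p14. A single symbol was found for 34892 probes and none for 23309, which gave 25006 genes, 7587 of them with several probes. The array's own grid uses another build, so no coordinates are given. Values are log2 signal minus the log2 75th percentile of the array, and a gene took the probe with the highest mean signal. A gene was tested when that probe was well above background on at least 2 arrays, which left 18177 of 25001 genes.

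All tests used limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparison of 6 detached with 4 attached arrays had the population as a block and 5 residual degrees of freedom. The difference between lines in the response to detachment was the interaction in a fit with 4. The 5 pairwise comparisons of culture states had the line as a block and 4 residual degrees of freedom, so the 2 lines stand in for replicates. The block takes out a constant difference between lines, and the error of a gene is how the lines differ in their response to the states. Beside each pairwise test, genes at least 2-fold apart in the same direction in both lines were counted without a test, among genes well above background on at least 1 of the 2 compared arrays in each line. The count that independent lines would give is the product of the lines' counts over that number of genes, for each direction and for opposite directions. Where the dimmer array was not well above background, a fold is a lower bound against the higher of its value and the lowest well-above-background signal of that array, written as at least N-fold.

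Gene lists for 36 themes were tested with camera (limma), which asks whether the genes of a list rank higher or lower than other genes, with the preset correlation of 0.01, and adjusted over the lists of a comparison. The lists hold 747 symbols, of which 13 had no named probe. Each call is given beside the adjusted p with an estimated correlation, and fry (limma) and an exact permutation over the 36 ways to call 1 array of each population attached were run too, the latter two-sided with a smallest possible p of 0.0278. Within a line, the median of a list was ranked among 10000 random lists matched on expression in 20 bins. Genes named in the text followed a rule. For each pairwise comparison these were the 10 genes per direction with the largest difference in the line where it was smaller, with 1 direction in both lines and a brighter array well above background. For the difference between lines they were the 10 lowest p per direction, and for 6 against 4 arrays the genes past the threshold with 1 direction in all arrays, of which there were 0. Symbols that begin with LOC, LINC or XLOC were passed over, and not all genes the rule gives are reported here. Members of the lists and genes known to tell the lines apart were also named. The comparisons, the lists, the rule for names and most alternatives were fixed before the data were examined.

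The alternatives were normexp background correction with an offset of 50, quantile normalization, the scaling of the deposited value table, no filter, a filter for genes well above background on all arrays, the mean over the probes of a gene, a slide block, no block, a random block, a variance trend with robust moderation, and leaving out each array. Scaling over probes detected on all arrays, leaving out both FL attached or both day 1 arrays, a slide block in the list test, leaving arrays out of the list test, and the exact permutation of lists were added after the data were seen. For normexp the median foreground signal was used in place of the mean that had been planned. A 2-fold count in both lines needs every array it compares, so none is given with such an array left out. On simulated data the comparison of 6 detached with 4 attached arrays recovered 53.7, 85.1 and 92.4 percent of genes planted 2-, 4- and 8-fold apart among 18177. For the line difference these were 1.49, 40.3 and 63.6 percent, and for the day 1 comparison 2.99, 44.8 and 72.7 percent. In the order of these comparisons, 12, 7 and 6 genes without a planted difference were also called. Each simulation planted 200 genes, each with 1 fixed difference, and drew normal noise independently for every gene and array. Genes of the real arrays are correlated, at an estimated 0.75 for mitosis genes in 6 against 4 arrays. Real differences can also vary between populations, so these percentages need not hold for the real arrays. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.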

Results

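Gene expression was measured in A549 and H441, lung adenocarcinoma cell lines, in 5 culture states with 1 array each. The states were attached, detached for 1 day, detached for 7 days, and an FL subline, selected on ultra-low attachment plates for more than 2 months, measured detached and attached. On each array 49.8 to 53.8 percent of the features were well above background. No group had a replicate array, so every standard error (SE) below comes from a fit that pools arrays over lines or populations, and the number of arrays limits the precision. Values are log2 intensities relative to the 75th percentile of the array. With the scaling of the deposited value table, the median of all genes in A549 shifted by 0.16 at day 1, 0.18 at day 7, 0.12 in FL detached and 0.21 in FL attached cells against parental attached cells. No list called below changed its direction under any scaling tried.

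Genes known to tell the lines apart did so in every culture state. AKR1B10, an aldo-keto reductase abundant in A549, stood at 9.96 ± 0.27 (SD, n = 5 arrays) in A549 and at -0.97 ± 0.36 in H441. NAPSA, an aspartic protease of lung epithelium, stood at -1.96 ± 0.31 in A549 and 7.15 ± 0.38 in H441. The exception among 11 such genes was the secretoglobin gene SCGB3A2, at 1.33 ± 0.39 and 1.26 ± 0.17.

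The broadest question was what the 6 detached arrays shared against the 4 attached arrays of the same populations. Genes of cell division were lower in detached cells, with 24 of 26 genes of mitosis and G2/M and 18 of 24 genes of S-phase and DNA replication lower in all 6 arrays. Of all 18177 genes, 2096 were lower and 1891 higher in all 6, and day 1 and day 7 of a line share an attached array. Genes of secretory and squamous cells, of the hypoxia response, of autophagy and the lysosome and of MHC presentation had higher medians, with 5 of 27, 7 of 26, 12 of 26 and 9 of 18 genes higher in all 6 arrays. Single genes did not pass the test over all genes. NEXN, which encodes an actin-binding protein, had the lowest adjusted p, 0.0834 (limma), at -1.82 ± 0.15 (SE), lower in 6 of 6 arrays.

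The mitosis list fell, with a median log2 difference of -0.76 (camera adjusted p = 2.2e-12, and adjusted p = 0.506 with an estimated correlation). PLK1, a mitotic kinase, had a difference of -1.15 ± 0.40 and CCNB1, the mitotic cyclin B1, -0.82 ± 0.20. Adjusted over the list alone, 21 of 26 genes passed, against 0 adjusted over all genes. The S-phase list fell as well, with a median of -0.57 (adjusted p = 1.01e-11, and adjusted p = 0.464 with an estimated correlation). Of its genes, 19 of 24 passed when adjusted over the list alone. UHRF1, which maintains DNA methylation at replication, had -1.29 ± 0.34, and MCM2, a subunit of the replicative helicase, -0.70 ± 0.18. Genes of ribosome biogenesis fell by a median of 0.40 (adjusted p = 2.05e-06, and adjusted p = 0.506 with an estimated correlation). Genes of ribosomal proteins rose, with a median of 0.23 (adjusted p = 5.7e-08, and adjusted p = 0.506 with an estimated correlation), which was 0.049 with quantile normalization.

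Targets of the mechanosensitive co-activators YAP and TAZ fell, with a median of -0.60 (adjusted p = 2.01e-05, and adjusted p = 0.506 with an estimated correlation). AJUBA, a LIM protein of cell junctions, had -1.43 ± 0.37, the receptor kinase AXL -1.17 ± 0.41 and the matricellular CCN1 -1.53 ± 0.57, each lower in 6 of 6 arrays, while IGFBP3, which binds insulin-like growth factors, had 1.69 ± 0.63. The extracellular matrix list fell, with a median of -0.44 (adjusted p = 0.0142, and adjusted p = 0.506 with an estimated correlation). The matrix glycoprotein THBS1 had -1.15 ± 0.19. Genes of SRF and the actin cytoskeleton fell, with a median of -0.19 (adjusted p = 0.0255, and adjusted p = 0.681 with an estimated correlation). Counts adjusted over the list alone were 0 YAP/TAZ targets, 6 of 27 matrix genes and 1 of 24 SRF genes.

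The list of secretory, goblet and squamous genes rose, with a median of 1.24 (adjusted p = 2.05e-06, and adjusted p = 0.464 with an estimated correlation). The median was 0.63 with normexp background correction. The trefoil peptide TFF1 had 2.03 ± 0.64 and the calcium-binding S100A9 2.04 ± 0.66, both higher in 6 of 6 arrays. Hypoxia response genes rose, with a median of 0.71 (adjusted p = 1.34e-06, and adjusted p = 0.506 with an estimated correlation), among them the carbonic anhydrase CA9 at 1.96 ± 0.52 and the MYC antagonist MXI1 at 1.13 ± 0.20. Their median was below 0, at -0.24, in 1 of the 6 arrays, A549 detached day 1. Autophagy and lysosome genes rose, with a median of 0.25 (adjusted p = 1.64e-06, and adjusted p = 0.432 with an estimated correlation), including WIPI1, which acts in autophagosome formation, at 2.08 ± 0.36 and the lysosomal enzyme HEXA at 0.89 ± 0.19. MHC presentation genes rose, with a median of 0.34 (adjusted p = 0.00125, and adjusted p = 0.464 with an estimated correlation), and HLA-C had 1.09 ± 0.23 and B2M, the shared light chain of MHC class I, 0.62 ± 0.19. Adjusted over the list alone, 1 of 27 secretory, 5 of 26 hypoxia, 6 of 26 autophagy and 7 of 18 MHC genes passed.

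Rises were called for 4 more lists. Endoplasmic reticulum chaperones rose (median 0.15, adjusted p = 0.00208, and adjusted p = 0.464 with an estimated correlation), as did fatty acid oxidation and PPAR targets (0.43, adjusted p = 0.00356, and adjusted p = 0.506 with an estimated correlation). The others were interferon-stimulated genes (0.39, adjusted p = 0.0117, and adjusted p = 0.506 with an estimated correlation) and p53 targets (0.25, adjusted p = 0.0255, and adjusted p = 0.681 with an estimated correlation). On single arrays of H441 a median went against the call for interferon genes (-0.0063 at day 1 and -0.16 at day 7), fatty acid oxidation (-0.066 at day 1), p53 targets (-0.024 at day 7) and SRF genes (0.26 in FL cells). The other 21 lists did not pass. Their medians were 0.42 for leukocyte markers, 0.23 for glycolysis, -0.27 for ATF4 and integrated stress response genes, 0.22 for epithelial junctions, 0.06 for oxidative phosphorylation, -0.26 for fatty acid synthesis, -0.17 for integrins, and 0.17 for immediate early genes. They were -0.10 for NF-kB and inflammatory cytokines, 0.32 for WNT targets, 0.09 for NRF2 targets, 0.24 for stem cell genes, -0.08 for the BCL2 family, -0.06 for cholesterol synthesis, -0.18 for fibroblast markers and 0.03 for endothelial markers. The TGF-beta list (-0.18), the EMT list (0.09) and the NOTCH list (-0.03) changed sign under another scaling. The median and the direction of the test differed for heat shock (-0.07), EMT and NOTCH genes, and the mean and the test differed for alveolar type II genes (median -0.12).

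The limma test found 0 genes past the threshold in 6 detached against 4 attached arrays, with 3447 of 18177 genes at an unadjusted p under 0.05. Genes well above background on all arrays, tested alone, gave 5 genes (LRP1, NEXN, SNORD47, TCP11L2 and TERT), and a random block gave 3 of these (NEXN, SNORD47 and TCP11L2), names chosen after their values were seen. Of the 15 list calls, none held with an estimated correlation and fry called 5.

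**Figure D1:**
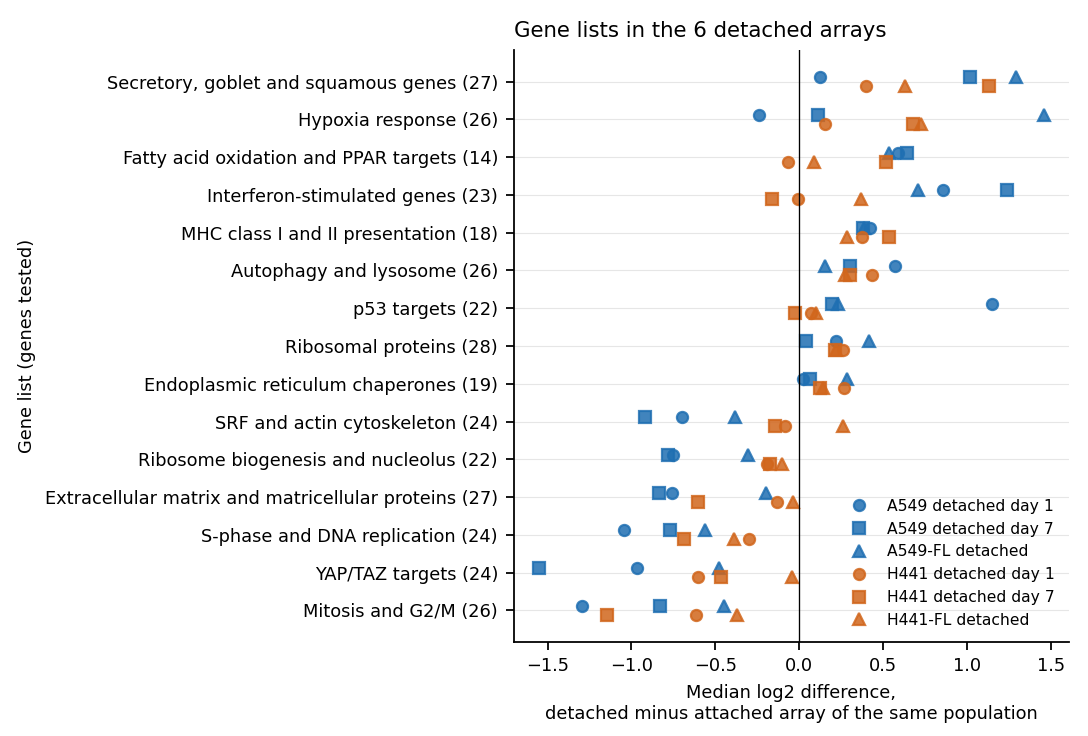
Median log2 difference of the tested genes of each list (number in brackets) between each of the 6 detached arrays and the attached array of its population, for the 15 lists called by camera, with A549 in blue and H441 in orange and the state as the symbol. The mitosis medians lie between -1.30 and -0.37 on all 6 arrays, and the secretory medians between 0.13 and 1.29.

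The next question was whether the lines differed in their response to detachment. PCK1, which encodes the cytosolic enzyme of gluconeogenesis, and KLRC3, a lectin-like receptor gene of natural killer cells, were higher in detached A549 cells and not in detached H441 cells. SNORD114-28, a small nucleolar RNA gene of an imprinted cluster, was lower in detached A549 cells. These 3 genes passed the limma test, each with an adjusted p of 0.0302. The error of this test is the spread over days and sublines of each line. No culture was repeated, so the p does not measure variation between repeated cultures. Of all genes tested, 6.39 percent had an unadjusted p under 0.05, near the share of 0.05 expected without any difference. PCK1 (RefSeq NM_002591) had a mean response of 4.54 in A549 and 0.34 in H441, a difference of -4.17 ± 0.27. KLRC3 (NM_007333) had 3.08 and -1.13, a difference of -4.25 ± 0.30, and SNORD114-28 (NR_003221) had -3.07 and 0.25, a difference of 3.31 ± 0.24. PCK1 was well above background on 3 of 10 arrays and SNORD114-28 on 2, all of A549, so their H441 values are background and the sizes of their differences are not bounds. Their SE and p rest in part on these background values.

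Among genes that did not pass, SFTPA2, a surfactant protein of alveolar type II cells that was measured above background on all arrays, had a mean response of 0.04 in A549 and 2.41 in H441 (adjusted p = 0.0672). In a comparison of lists, interferon-stimulated genes responded more in A549, with a median difference of -0.73 for H441 minus A549 (adjusted p = 0.000227, and adjusted p = 0.734 with an estimated correlation). IFIT1, an interferon-induced RNA-binding protein, differed by 3.02, 1.91 and 1.05 on the 3 detached A549 arrays and by -0.37, -0.85 and 0.08 on those of H441. Fatty acid oxidation and PPAR targets (-0.37) and p53 targets (-0.31) also responded more in A549 (adjusted p = 0.00317 and 0.0213, and adjusted p = 0.734 and 0.770 with an estimated correlation). MHC genes were called with a median difference of -0.32 (adjusted p = 0.0322, and adjusted p = 0.734 with an estimated correlation). Their array medians showed no larger response in A549. At day 1, day 7 and in FL cells these were 0.42, 0.38 and 0.39 in A549 and 0.37, 0.54 and 0.28 in H441. NF-kB and inflammatory cytokine genes had a median difference of 0.92 (adjusted p = 0.000162, and adjusted p = 0.734 with an estimated correlation). The chemokine CXCL8 stood 2.21 higher in H441 and differed by -0.84 in A549 at day 1. SRF and actin genes (0.65, adjusted p = 2.14e-05, and adjusted p = 0.734 with an estimated correlation) and YAP/TAZ targets (0.62, adjusted p = 0.00327, and adjusted p = 0.734 with an estimated correlation) also differed, with a larger fall in A549.

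Positive differences were also called for genes of ribosome biogenesis (0.45, adjusted p = 0.000162, and adjusted p = 0.734 with an estimated correlation), ATF4 (0.56, adjusted p = 0.00157, and adjusted p = 0.770 with an estimated correlation) and S-phase (0.36, adjusted p = 0.0213, and adjusted p = 0.770 with an estimated correlation). The same held for TGF-beta targets (0.35, adjusted p = 0.0254, and adjusted p = 0.734 with an estimated correlation) and EMT genes (0.54, adjusted p = 0.0269, and adjusted p = 0.734 with an estimated correlation). Over these lists, 5 EMT genes, 1 YAP/TAZ target and 1 TGF-beta target passed when adjusted over the list alone, against 0 adjusted over all genes. The count of 3 genes became 0 with any 1 array left out and 8 with the mean over the probes of a gene, and 1162 genes had an unadjusted p under 0.05.

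After 1 day of detachment, the response common to both lines was again led by lower genes of cell division. Among single genes, TUBGCP3, a subunit of the gamma-tubulin ring complex that nucleates microtubules, was 17.3-fold lower in A549 and 7.62-fold lower in H441, and IFT56, of the intraflagellar transport that builds cilia, was at least 18.7-fold and 7.07-fold lower. IFT46, of the same transport complex, had a mean difference of -3.14 ± 0.27. Among higher genes, TMEM198, a membrane protein gene, was 27.6-fold and 9.92-fold higher, TNFRSF8, the lymphoma antigen CD30, 9.27-fold and at least 17.2-fold, and the trypsin inhibitor SPINK1 at least 4.27-fold and 12.6-fold. The pseudogene CDIPTOSP was at least 35.4-fold and at least 6.28-fold higher.

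At day 1 the mitosis list fell, with a median of -0.88 and 24 of 26 genes lower in both lines (adjusted p = 1.16e-10, and adjusted p = 0.774 with an estimated correlation). PLK1 differed by -2.77 in A549 and -1.37 in H441. S-phase genes fell (-0.64, 18 of 24 lower in both, adjusted p = 3.31e-06, and adjusted p = 0.774 with an estimated correlation). So did genes of ribosome biogenesis (-0.47, 17 of 22, adjusted p = 0.000326, and adjusted p = 0.795 with an estimated correlation). YAP/TAZ targets fell (-0.78, 18 of 24, adjusted p = 0.000441, and adjusted p = 0.774 with an estimated correlation), among them FJX1, a secreted signalling protein, at -2.89 and -2.12. Genes of integrins and focal adhesions fell (-0.46, 12 of 24, adjusted p = 0.00818, and adjusted p = 0.714 with an estimated correlation), with the integrin-linked kinase ILK at -1.69 and -1.35 and CAV1, the coat protein of caveolae, at -1.73 and -1.48. Autophagy and lysosome genes rose (0.47, 18 of 26 higher in both, adjusted p = 6.36e-05, and adjusted p = 0.714 with an estimated correlation), including the ATG8-family gene GABARAPL1 at 3.20 and 1.40. Ribosomal protein genes were higher in 28 of 28 cases (0.24, adjusted p = 0.000326, and adjusted p = 0.795 with an estimated correlation), with a median of 0.075 under quantile normalization. MHC genes rose too (0.40, adjusted p = 0.0294, and adjusted p = 0.714 with an estimated correlation).

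The p53 targets rose by a median of 0.51 (adjusted p = 0.00146, and adjusted p = 0.795 with an estimated correlation). Their median was 1.15 in A549 and 0.07 in H441, which stood at the 100th and the 72.6th percentile of random lists. CDKN1A, the cyclin-dependent kinase inhibitor p21, differed by 1.66 and 0.12, and the p53 inhibitor MDM2 by 1.77 and 0.76. Adjusted over the list alone, 11 mitosis genes, 4 p53 targets, 2 YAP/TAZ targets, 2 integrin genes, 1 autophagy gene and 0 S-phase genes passed. In both lines 272 genes were at least 2-fold higher and 394 at least 2-fold lower among 15487, where independent lines would give 63.7 and 96.6, and 117 genes went opposite ways, against 159 for independent lines. Across genes the differences of the lines had a Pearson correlation of 0.409, although genes are not independent replicates. The limma test over both lines called 0 genes, with 2955 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0892. It called 210 with normexp background correction, which also brought the total for day 1 detached vs attached, 2-fold in both lines, from 666 to 279.

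After 7 days, several of the genes that differed most in both lines encode secreted proteins. PIP, the prolactin-induced protein of exocrine secretions, was at least 116-fold higher in A549 and at least 115-fold higher in H441, and TCN1, a vitamin B12-binding protein of secretions, at least 88.5-fold and 330-fold. GSTA5, a glutathione transferase gene, was at least 16.2-fold and at least 16.9-fold higher, the copper carrier CP 16.1-fold and 29.6-fold, and BPIFB1, an airway secretory protein, at least 5.20-fold and at least 24.1-fold. Among lower genes, VSTM1, an immunoglobulin-domain receptor gene, was 48.2-fold lower in A549 and at least 9.91-fold lower in H441. COL12A1, a fibril-associated collagen, was 5.14-fold and 6.66-fold lower.

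Secretory, goblet and squamous genes rose at day 7, with a median of 2.02, and 20 of 27 were higher in both lines, 9 of them at least 2-fold (adjusted p = 2.01e-06, and adjusted p = 0.157 with an estimated correlation). The medians within the lines were 1.02 in A549 and 1.13 in H441, and the common median was 0.93 with normexp. The mucin MUC5AC differed by 2.60 and 2.84, the trefoil peptide TFF3 by 5.21 and 2.59, and AGR2, which folds mucins, by 3.12 and 2.28. All 26 mitosis genes were lower in both lines (-1.02, adjusted p = 5.27e-14, and adjusted p = 0.439 with an estimated correlation). Lower in both lines were also 23 of 24 S-phase genes (-0.75, adjusted p = 3.62e-11, and adjusted p = 0.439 with an estimated correlation) and 19 of 22 genes of ribosome biogenesis (-0.55, adjusted p = 1.13e-05, and adjusted p = 0.519 with an estimated correlation). YAP/TAZ targets fell (-1.11, 20 of 24, adjusted p = 3.53e-07, and adjusted p = 0.439 with an estimated correlation), with AJUBA at -2.93 and -1.88. Extracellular matrix genes (-0.78, adjusted p = 0.00959), integrin genes (-0.28, adjusted p = 0.0389) and SRF and actin genes (-0.41, adjusted p = 0.00858) fell as well, with an adjusted p = 0.439, 0.439 and 0.519 with an estimated correlation. The integrin median in A549 (percentile 20.3 of random lists), the SRF (8.73) and ribosome biogenesis medians (6.65) in H441 and the chaperone medians in A549 (94.8) and H441 (89.0) lay between the 5th and the 95th percentile within the line.

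Of the metabolic lists, glycolysis (adjusted p = 0.691), oxidative phosphorylation (0.675) and fatty acid synthesis (0.0532) were not called at day 7. Fatty acid oxidation and PPAR targets rose (0.71, 8 of 14 higher in both lines, adjusted p = 0.000303, and adjusted p = 0.439 with an estimated correlation). CPT1A, which admits fatty acids to mitochondria, differed by 1.30 and 0.60. Genes of the integrated stress response around ATF4 fell (-0.56, 17 of 25, adjusted p = 0.000254, and adjusted p = 0.519 with an estimated correlation), with ASNS of asparagine synthesis at -2.04 and -0.59 and the amino acid transporter SLC7A5 at -2.12 and -0.92. Cholesterol synthesis genes fell (-0.43, 17 of 24, adjusted p = 0.00852, and adjusted p = 0.519 with an estimated correlation), with medians of -0.22 in A549, at the 39.7th percentile of random lists, and -0.47 in H441. Hypoxia response genes rose (0.55, 14 of 26, adjusted p = 0.000715, and adjusted p = 0.519 with an estimated correlation), with CA9 at 3.10 and 2.57. Autophagy genes rose (0.34, 15 of 26, adjusted p = 0.000283, and adjusted p = 0.439 with an estimated correlation). Immediate early genes rose (0.39, adjusted p = 0.0216, and adjusted p = 0.519 with an estimated correlation), with medians of -0.45 in A549 and 0.89 in H441, and the transcription factor FOS at 3.47 and 3.07. Small rises were called for ribosomal proteins (0.12, or 0.0028 under quantile normalization, adjusted p = 0.00775, and adjusted p = 0.622 with an estimated correlation) and endoplasmic reticulum chaperones (0.13, adjusted p = 0.0245, and adjusted p = 0.519 with an estimated correlation).

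Adjusted over the list alone, 18 mitosis, 14 S-phase, 6 YAP/TAZ, 3 immediate early, 2 chaperone, 1 autophagy, 1 matrix and 1 secretory gene passed at day 7, against 0 of these adjusted over all genes. VSTM1 (NM_198481) alone passed the limma test over all genes, at -5.25 ± 0.30 (n = 2 lines, adjusted p = 0.0344), and 2115 genes had an unadjusted p under 0.05. VSTM1 was not well above background on the H441 day 7 array, so this difference, its SE and its p rest in part on a background value. It did not pass with any 1 array left out or with normexp. In both lines 319 genes were at least 2-fold higher and 184 lower among 15470, where independent lines would give 66.2 and 47.5, and 105 went opposite ways, against 112 for independent lines. The total for day 7 detached vs attached, 2-fold in both lines, was 503 and became 173 with normexp and 301 when all arrays had to be well above background.

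**Figure D2:**
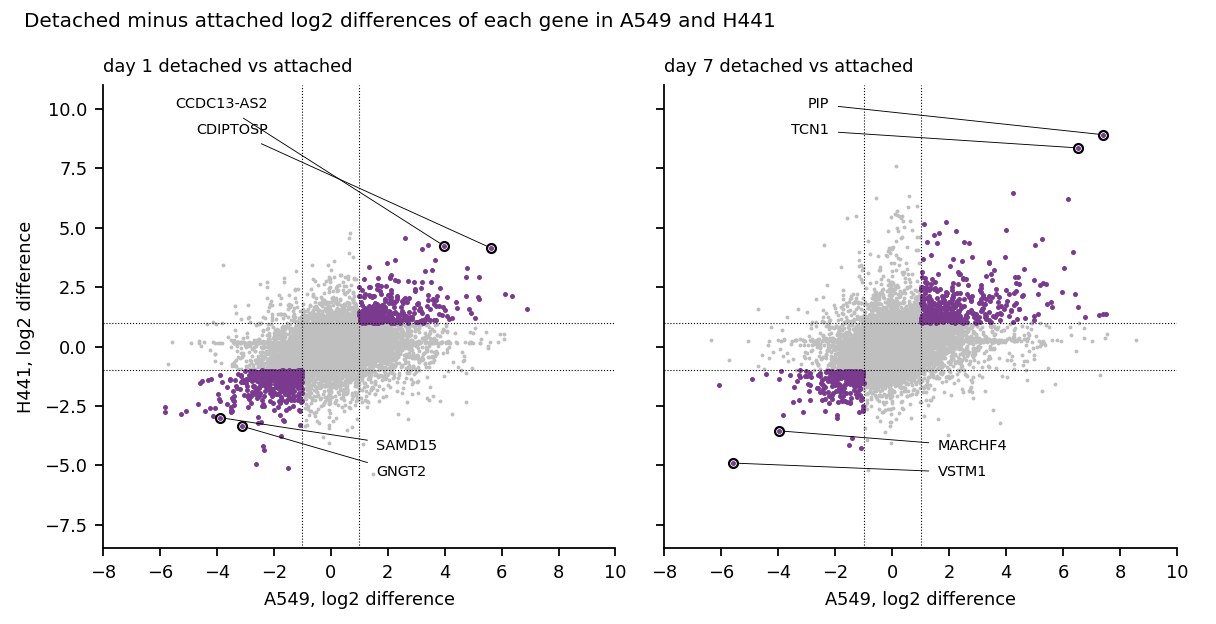
Log2 difference between detached and attached cells in A549 (x axis) and H441 (y axis) for each of 18177 tested genes, at day 1 (left) and day 7 (right). Purple points lie at least 1 from 0 in the same direction in both lines, including genes too dim for the 2-fold counts, and open circles mark the 2 genes per direction that the rule for names ranks first, with PIP and TCN1 at the top right at day 7.

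The FL sublines, measured detached, were compared with the attached parental lines. Prolonged culture without attachment and the detached state itself cannot be told apart in this comparison. PIP and TCN1 were again far higher, at least 114-fold and at least 37.0-fold for PIP and at least 80.7-fold and 391-fold for TCN1. The calcium-binding S100A9 was 927-fold higher in A549-FL and 22.1-fold higher in H441-FL, the complement factor gene CFB 78.7-fold and 16.8-fold, and SERPINB3, a serpin of squamous epithelium, 218-fold and at least 4.10-fold. LTB, which encodes the cytokine lymphotoxin beta, was at least 20.1-fold and 255-fold lower, IL32, a proinflammatory cytokine, 11.9-fold and 24.5-fold, and VSTM1 51.8-fold and at least 11.2-fold.

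Hypoxia response genes rose in detached FL cells (0.99, 21 of 26 higher in both lines, adjusted p = 1.41e-08, and adjusted p = 0.546 with an estimated correlation), with ANKRD37 at 2.49 and 2.85 and NDRG1 at 1.71 and 1.68, both induced by low oxygen. MHC presentation genes rose (1.24, with 0.49 in A549 and 0.75 in H441, 12 of 18, adjusted p = 2.64e-05, and adjusted p = 0.242 with an estimated correlation), with HLA-DMB, which helps load peptides on class II molecules, at 7.02 and 3.68 and HLA-C at 2.62 and 1.02. Leukocyte markers rose with them (0.51, adjusted p = 0.0481, and adjusted p = 0.546 with an estimated correlation). CD14, a co-receptor for bacterial lipopolysaccharide, differed by 2.43 and 4.65. Secretory, goblet and squamous genes rose (1.57, with 0.74 in A549 and 0.93 in H441, or 0.69 with normexp, 17 of 27, adjusted p = 4.25e-05, and adjusted p = 0.242 with an estimated correlation), although the cornified envelope gene SPRR3 differed by 0.74 in A549 and 9.14 in H441. Glycolysis (0.42, adjusted p = 0.00739), autophagy (0.27, adjusted p = 0.000592), chaperone (0.10, adjusted p = 0.0206), immediate early (0.52, adjusted p = 0.0355) and NOTCH genes (0.17, adjusted p = 0.0443) rose with an adjusted p = 0.546 each with an estimated correlation. Cholesterol synthesis genes rose (0.19, adjusted p = 0.0355, and adjusted p = 0.564 with an estimated correlation). Interferon-stimulated genes rose (0.81, adjusted p = 0.00791, and adjusted p = 0.546 with an estimated correlation), although their median was -0.09 in H441. Within 1 line, ribosome biogenesis (percentile 12.8 of random lists), glycolysis (92.3) and chaperones (81.8) in H441 and leukocyte markers (80.0), NOTCH (93.7) and cholesterol genes (93.1) in A549 lay between the 5th and the 95th percentile.

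NF-kB and inflammatory cytokine genes fell in detached FL cells (-0.93, 16 of 22 lower in both lines and 8 at least 2-fold, adjusted p = 0.00739, and adjusted p = 0.553 with an estimated correlation), with the chemokine CXCL2 at -1.51 and -1.49. YAP/TAZ targets fell (-0.94, 15 of 24, adjusted p = 5.29e-06, and adjusted p = 0.546 with an estimated correlation), with AXL at -2.73 and -1.62. Mitosis genes (-0.81, 25 of 26, adjusted p = 6.92e-08), S-phase genes (-0.75, 21 of 24, adjusted p = 1.55e-07), ribosome biogenesis (-0.69, 16 of 22, adjusted p = 1.29e-05) and ATF4 genes (-0.60, 15 of 25, adjusted p = 0.0082) fell with an adjusted p = 0.546 each with an estimated correlation. Of these lists, 10 YAP/TAZ targets, 6 hypoxia, 5 MHC, 4 mitosis, 2 S-phase and 2 interferon genes passed when adjusted over the list alone, as did 1 autophagy, 1 secretory, 1 immediate early and 1 NOTCH gene, against 0 adjusted over all genes. VSTM1 alone passed the limma test over all genes (-5.62 ± 0.30, n = 2 lines, adjusted p = 0.0229), with 2896 genes at an unadjusted p under 0.05. VSTM1 was not well above background on the H441-FL detached array, so these values too rest in part on a background value. It was not called with normexp, and without the A549 attached array LTB was called in its place. In both lines 355 genes were at least 2-fold higher and 262 lower among 15439, where independent lines would give 108 and 95.4, and 268 went opposite ways, against 203 for independent lines. The total for FL detached vs parental attached, 2-fold in both lines, was 617 and became 223 with normexp and 377 when all arrays had to be well above background.

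The FL sublines in standard culture were compared with the attached parental lines, which asks what differs when both are attached. Inflammatory genes were lower, among them LTB, at least 22.4-fold in A549 and 52.7-fold in H441, the cytokine IL6, at least 6.10-fold and 10.3-fold, and TNFRSF9, a receptor of the tumour necrosis factor family, 10.9-fold and 5.90-fold. VSTM1 was 10.7-fold and 12.5-fold lower. HLA-DMB was 78.5-fold and 11.7-fold higher, NCALD, a neuronal calcium sensor, 7.61-fold and 6.75-fold, and the glucose transporter SLC2A3 5.21-fold and at least 11.5-fold.

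NF-kB and inflammatory cytokine genes fell (-0.94, 16 of 22 lower in both lines, adjusted p = 0.000253, and adjusted p = 0.720 with an estimated correlation), with CXCL1 at -1.13 and -1.97. YAP/TAZ targets fell (-0.73, 15 of 24, adjusted p = 8.21e-05, and adjusted p = 0.720 with an estimated correlation), with AJUBA at -1.53 and -1.61. Ribosome biogenesis (-0.36, 15 of 22, adjusted p = 0.000253), ribosomal protein (-0.24, 24 of 28, adjusted p = 0.00072) and mitosis genes (-0.42, 21 of 26, adjusted p = 0.000969) fell with an adjusted p = 0.720 each with an estimated correlation. Heat shock genes fell (-0.41, adjusted p = 0.0369, and adjusted p = 0.720 with an estimated correlation), with medians of -0.96 in A549 and 0.03 in H441. MHC genes (0.26) and NOTCH genes (0.18) rose (adjusted p = 0.0145 each, and adjusted p = 0.638 each with an estimated correlation), with medians of 0.017 and 0.045 in A549-FL and 0.24 and 0.32 in H441-FL. Within 1 line, ribosomal proteins in A549-FL (percentile 32.4 of random lists) and ribosome biogenesis in H441-FL (25.6) lay between the 5th and the 95th percentile. Fibroblast markers went opposite ways, with medians of 1.39 in A549-FL and -0.74 in H441-FL. Of the called lists, 5 YAP/TAZ targets, 1 MHC and 1 NOTCH gene passed when adjusted over the list alone. The limma test called 0 genes, with 1121, or 6.17 percent, at an unadjusted p under 0.05. That is near the share of 0.05 expected without any difference. In both lines 137 genes were at least 2-fold higher and 96 lower among 15589, where independent lines would give 42.7 and 36.6, while 225 went opposite ways, against 79.5 for independent lines. Across genes the lines' differences had a Pearson correlation of 0.038, so no direction was shared over all genes. The FL attached arrays were the only ones of slide 2, so slide and this state are confounded. The FL detached arrays, on slide 1 with the parental arrays, also had lower NF-kB genes (-0.93) and higher HLA-DMB (7.02 and 3.68) than attached parental cells. Both comparisons use the same attached parental arrays, so they are not independent. The total for FL attached vs parental attached, 2-fold in both lines, went from 233 to 58 with normexp, to 116 when all arrays had to be well above background and to 483 without a filter.

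Within the FL sublines, detached cells were compared with attached cells to see which differences depend on attachment itself. TREM1, an amplifying receptor of inflammation, was 53.7-fold higher in A549-FL and 8.54-fold higher in H441-FL, TCN1 23.5-fold and 11.9-fold, PIP 7.07-fold and 31.5-fold, and ANGPTL4, an inhibitor of lipoprotein lipase, 8.70-fold and 9.17-fold. CEACAM5, the carcinoembryonic antigen, was 10.1-fold and 6.33-fold higher. The phospholipid flippase gene ATP10A was 5.08-fold and 4.97-fold lower, and SCARNA13, a small Cajal body RNA gene, 4.06-fold and 4.10-fold.

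Hypoxia response genes rose (1.02, 24 of 26 higher in both lines, adjusted p = 3.73e-16, and adjusted p = 0.519 with an estimated correlation), with NDRG1 at 1.75 and 1.54 and ANKRD37 at 2.33 and 2.42. Glycolysis genes rose (0.30, 15 of 17, adjusted p = 6.54e-05, and adjusted p = 0.650 with an estimated correlation). Secretory, goblet and squamous genes rose (1.28, or 0.66 with normexp, 17 of 27, adjusted p = 9.57e-05, and adjusted p = 0.301 with an estimated correlation), with S100A9 at 1.81 and 2.43. Ribosomal protein genes were higher in 28 of 28 cases (0.31, or 0.063 under quantile normalization, adjusted p = 9.55e-11, and adjusted p = 0.650 with an estimated correlation). Rises were also called for MHC (0.35, adjusted p = 0.00145), chaperone (0.25, adjusted p = 0.00145), autophagy (0.16, adjusted p = 0.00124), fatty acid oxidation (0.31, adjusted p = 0.0166), interferon (0.42, adjusted p = 0.0471) and oxidative phosphorylation genes (0.14, adjusted p = 0.0471), with an adjusted p = 0.519, 0.650, 0.650, 0.650, 0.664 and 0.664 with an estimated correlation. The oxidative phosphorylation median was 0.24 in A549-FL and -0.03 in H441-FL, and the common median was 0.0025 under quantile normalization. The fatty acid oxidation medians were 0.53 and 0.09.

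S-phase genes were lower in 24 of 24 cases (-0.48, adjusted p = 2.47e-10, and adjusted p = 0.650 with an estimated correlation), with GINS2, of the replicative helicase, at -0.70 and -0.54. Mitosis genes were lower in 26 of 26 (-0.40, adjusted p = 9.61e-07, and adjusted p = 0.664 with an estimated correlation). Falls were called for ribosome biogenesis (-0.22, adjusted p = 0.0166), YAP/TAZ (-0.35, adjusted p = 0.0185) and ATF4 genes (-0.27, adjusted p = 0.0176), with an adjusted p = 0.720, 0.664 and 0.664 with an estimated correlation, with medians near 0 in H441-FL for YAP/TAZ (-0.48 in A549-FL and -0.04 in H441-FL) and ATF4 genes (-0.74 and 0.00091). The limma test called 0 genes, and 0 members of the 15 called lists passed when adjusted over the list alone. At an unadjusted p under 0.05 there were 794 genes, or 4.37 percent. That is no more than the share of 0.05 expected without any difference. In both lines 118 genes were at least 2-fold higher and 75 lower among 15349, where independent lines would give 13.4 and 6.51, and 24 went opposite ways, against 18.7 for independent lines. Slide and attachment are confounded here too. The total for FL detached vs FL attached, 2-fold in both lines, went from 193 to 37 with normexp, to 85 when all arrays had to be well above background and to 431 without a filter. Across genes, and with no shared array, these differences correlated with those at day 7 at 0.53 in A549 and 0.44 in H441, and with those at day 1 at 0.33 and 0.20.

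**Figure D3:**
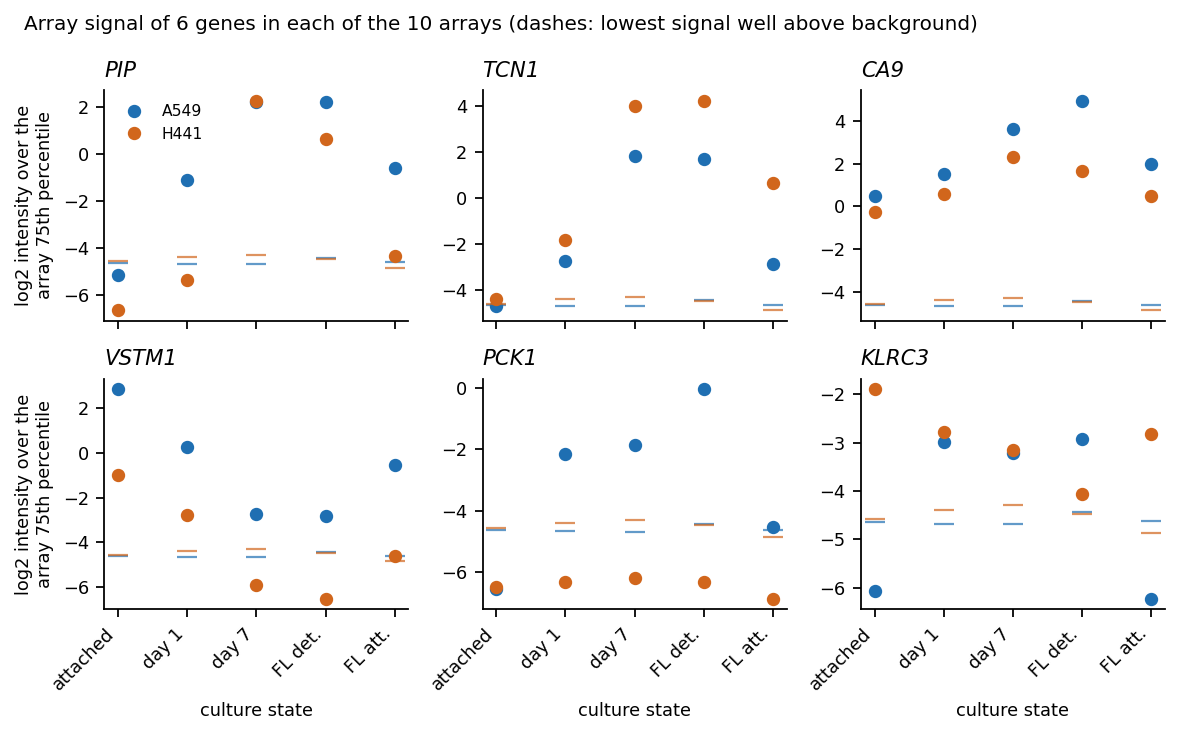
Log2 intensity relative to the array's 75th percentile (y axis) of 6 genes on each of the 10 arrays, with a dash at the lowest signal called well above background on that array. PIP and TCN1 lie near or below the dash in attached parental cells and far above it at day 7 and in detached FL cells of both lines.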

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

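The tests of other splits of the 10 arrays, of slides, of scaling, of probes and of the conflicting description were chosen only after the results they concern were seen, and the test of other pairings of the populations was chosen before.

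Results are listed here because the response to detachment differed between A549 and H441. For single genes the difference, H441 minus A549, passed the test for SNORD114-28 (3.31), PCK1 (-4.17) and KLRC3 (-4.25). Of the 3 pairings of the 4 populations, 1, the real pairing by line, gave as many genes, with 3 genes against 0 in the highest other pairing, and 3 pairings are too few for a share under 0.05. Genes with all 3 detached arrays of A549 moving one way and all 3 of H441 the other, which did not pass the test, were LHFPL6 (3.67), TENM2 (2.73), SFTPA1 (3.08), SNORD114-22 (2.55), ALOX5AP (3.21), GSC (2.70), LAPTM5 (-3.64), KLRC4 (-3.50) and CHGB (-3.81). Among them SFTPA1 encodes a surfactant protein, KLRC4 a natural killer receptor of the KLRC3 gene cluster, and CHGB a granin of secretory vesicles. No H441 array was well above background for LHFPL6, TENM2, SNORD114-22, ALOX5AP, GSC and CHGB, and no A549 array for SFTPA1, so a direction in that line was not measured and the sizes are not exact.

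Gene lists whose response differed between the lines by camera had the following median differences, and 0 of these calls held with an estimated correlation. Genes of SRF and actin differed by 0.65, NF-kB and inflammatory cytokines by 0.92, YAP/TAZ targets by 0.62, ATF4 genes by 0.56, EMT genes by 0.54, ribosome biogenesis by 0.45, S-phase by 0.36 and TGF-beta targets by 0.35. Interferon-stimulated genes differed by -0.73, fatty acid oxidation and PPAR targets by -0.37, MHC genes by -0.32 and p53 targets by -0.31.

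In single comparisons, some lists had medians of opposite direction in the lines, a difference that was not tested for that comparison alone. Over all detached arrays, camera called the difference between the lines for the NF-kB and SRF lists, as given above, and not for immediate early genes (adjusted p = 0.132) or cholesterol synthesis (adjusted p = 0.418). NF-kB and inflammatory cytokines differed by 1.18 at day 1 (-0.70 in A549 and 0.48 in H441) and by 1.62 at day 7 (-1.37 and 0.26). Immediate early genes differed by 1.14 at day 1 (-0.61 and 0.54). Between FL detached and FL attached cells, cholesterol synthesis differed by 0.63 (-0.24 and 0.39) and SRF and actin genes by 0.64 (-0.38 and 0.26). Fibroblast markers differed by -2.13 between FL attached and parental attached cells (1.39 and -0.74). NOTCH genes had array medians that were opposite in all 3 arrays of each line, with means 0.33 apart, and camera did not call their difference between the lines (median 0.23, adjusted p = 0.699).

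A signal also appeared in probes with no gene name, which the comparisons of genes leave out. Of these, 5107 were well above background on all 10 arrays, against 2 of 3080 negative control spots.

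Many genes were at least 2-fold apart at day 1 in both lines, 666 in all, among them TMEM198, TUBGCP3 and SPINK1. Chance binding of single probes would leave other probes of these genes near 0, and the smallest of the 4 medians of those probes was 1.13 in the direction of the chosen probe. Another probe existed for 51 of the 272 higher and 99 of the 394 lower genes, so the rest, TMEM198 and SPINK1 among them, were not tested. The A549 day 1 array had a spike-in detection limit out of range, but an effect of 1 array would not reach H441, and across genes the lines' differences correlated at 0.41. A response to loss of attachment is a candidate explanation, and dissociation with trypsin before plating stays open, since no array of cells dissociated and plated again on an attaching surface was used here.

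Genes of mitosis were lower in detached arrays, with PLK1 and CCNB1 among them. A slide effect would leave the parental lines, all on slide 1, near 0, and their mean of array medians was -0.97. Scaling between arrays would bring the median near 0 in another scaling, and the value nearest 0 over all scalings was -0.72. Less cell division without attachment may explain it. Cell density and time since plating were not tested.

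Detached FL cells differed from attached FL cells alike in both lines, with TCN1, PIP and ANGPTL4 higher. A slide effect would enter FL attached minus parental attached cells too, and its covariance between the lines was 14.7 percent of that of FL detached minus FL attached. This cannot decide on a slide effect, since that difference also holds the changes of each subline. In it 225 genes went opposite ways, against 79.5 for independent lines, which lowers the covariance. The description of the FL attached samples says that the cells were detached, against their titles, and such cells would not repeat the day 7 response, yet the lower of the lines' correlations across genes with day 7 was 0.44. An effect of attachment is a candidate explanation. For ribosomal protein genes the slide cannot be told apart from it, since their medians in FL attached minus parental attached cells were at most -0.25 in the lines and each slide effect is confounded with FL attached culture.

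Of 100 splits of the 10 arrays into 6 and 4, drawn from 210 possible, 100 gave at least as many genes past the threshold as the real split, which gave 0 by limma, against 327 in the highest other split, but with a real count of 0 no other outcome was possible, so these splits decide nothing about it. At an unadjusted p under 0.05 the real split had 3447 genes, the highest other split 3252, and the highest other of the 36 arrangements within populations 2448. The split with 327 set A549 day 1, H441 day 1, H441-FL detached and H441-FL attached apart from the rest. Both arrays of each FL subline lay on the same side, and the population was a block. Its difference was thus between the day 1 arrays and the attached and day 7 arrays of the parental lines. A count so far above the real one points to this structure of the samples, whose cause was not tested.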

How the results depend on the processing

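Scaling over detected probes, arrays left out in the list test, both FL attached or both day 1 arrays left out, the slide block in the list test and the exact permutation of lists were chosen only after the results were seen. No paired analysis was possible by replicate number because each group holds 1 array, and pairing by line or population enters each fit as its block.

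No called list and no named gene reversed under the alternatives scored for it. The direction of named genes was not scored with normexp. Among lists not called, some medians changed sign under another scaling, as given above for 6 detached against 4 attached arrays. Of 92 list calls over all comparisons, 90 held with the deposited scaling, 88 with scaling over detected probes, 79 with quantile normalization, 78 with normexp and 8 with fry. With an estimated correlation 0 held. Some alternatives could be fitted only for part of the calls. Without both day 1 arrays 69 held and 14 did not, and without both FL attached arrays 68 held and 1 did not. With a slide block in the list test 27 held. All 100 named gene values kept their sign and their side of the threshold under the deposited scaling and scaling over detected probes. Both scalings shift each array by 1 constant, and the named genes were chosen for large differences, so they could hardly change a sign. Under quantile normalization 99 held and 1 passed the threshold in addition. For the gene lists of 6 detached against 4 attached arrays, of which 15 were called, an estimated correlation gave 0, fry 5 and the exact permutation within populations 0, where the smallest p it can give, 0.0278, was 0.125 after adjustment. Of the called lists, 8 reached that smallest p. Secretory and matrix genes had an unadjusted permutation p of 0.0556 each. Fatty acid oxidation and interferon genes had 0.0833 each, hypoxia genes 0.167, SRF genes 0.194 and p53 targets 0.222. Leaving out 1 array gave 14 to 19, and 19 came without the H441 attached array, 15 of them shared with the 15.

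For the limma tests, counts of genes past the threshold changed as follows, and the cause was not tested except where stated. For detached vs attached in 4 cell populations (0), well above background on all 10 arrays gave 5 and a random block 3. For line difference in the detachment response (3), normexp gave 1, quantile normalization 5, the mean of all probes of a gene 8, and each of well above background on all 10 arrays, slide block, no block, random block, and intensity trend with robust variances gave 0. The filter removes all 3 genes by construction, since none was measured on all arrays. Without both FL attached arrays or without both day 1 arrays it gave 0, as did each array left out, 0 to 0.

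For day 1 detached vs attached, both lines (0), normexp background correction gave 210, well above background on all 10 arrays 191, a random block 6 and intensity trend with robust variances 70. For day 7 detached vs attached, both lines (1), normexp, well above background on all 10 arrays, no block and random block each gave 0. For FL detached vs parental attached, both lines (1), quantile normalization gave 2, well above background on all 10 arrays 4, the mean of all probes 3 and intensity trend with robust variances 2, while normexp, no block and random block gave 0. Leaving out 1 array gave 0 to 1 there, with LTB in place of VSTM1 when the A549 attached array was left out, and 0 to 0 in each of the other tests between lines. A lone array is then assumed to vary like the others. Both tests of FL attached cells, against parental and against FL detached cells, gave 0 under every alternative that could be fitted. With slide as a block they could not be fitted.

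For genes 2-fold in both lines, normexp gave 279 for day 1 detached vs attached, 2-fold in both lines (666), 173 for day 7 detached vs attached, 2-fold in both lines (503), 223 for FL detached vs parental attached, 2-fold in both lines (617), 58 for FL attached vs parental attached, 2-fold in both lines (233) and 37 for FL detached vs FL attached, 2-fold in both lines (193). Well above background on all 10 arrays gave 301, 377, 116 and 85 for the last 4 in that order. No filter on dim probes gave 483 and 431 for the last pair, and fewer or more dim genes are counted by construction of these filters. Leaving out 1 array gives no value here. Signal over background limits these counts, since 49.8 to 53.8 percent of features were well above it.

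Medians of some called lists moved by more than 1.5 times without a change of sign, beside those in the report, and the cause was not tested. With normexp, interferon-stimulated genes went from 0.39 to 0.20 in 6 against 4 arrays and from 0.81 to 0.42 in FL detached against parental attached cells. For the line difference, NF-kB genes went from 0.92 to 0.48, interferon genes from -0.73 to -0.37, EMT genes from 0.54 to 0.29, TGF-beta targets from 0.35 to 0.23 and p53 targets from -0.31 to -0.19. YAP/TAZ targets went from -0.78 to -0.49 at day 1, from -1.11 to -0.71 at day 7, from -0.73 to -0.47 in FL attached against parental attached cells and from -0.35 to -0.20 within the FL sublines. Immediate early genes went from 0.39 to 0.19 at day 7. In FL detached against parental attached cells, immediate early genes went from 0.52 to 0.27, leukocyte markers from 0.51 to 0.33, cholesterol synthesis from 0.19 to 0.11 and NF-kB genes from -0.93 to -0.62. NF-kB genes went from -0.94 to -0.62 in FL attached cells. With quantile normalization, oxidative phosphorylation went from 0.14 to 0.0025 and glycolysis from 0.30 to 0.18 within the FL sublines, integrins from -0.28 to -0.18 at day 7, and S-phase genes from 0.36 to 0.24 in the line difference. In FL attached against parental attached cells ribosomal proteins went from -0.24 to -0.064, mitosis from -0.42 to -0.27 and heat shock from -0.41 to -0.25 with it. Chaperones went from 0.13 to 0.22 at day 7, from 0.10 to 0.20 in FL detached against parental attached cells and from 0.25 to 0.16 within the FL sublines. With the deposited scaling, autophagy went from 0.16 to 0.096 within the FL sublines. In FL attached against parental attached cells MHC went from 0.26 to 0.40, NOTCH from 0.18 to 0.32 (0.077 with normexp) and ribosome biogenesis from -0.36 to -0.23.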

Other observations

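The test of snoRNA genes below was chosen only after the result was seen, and the other values here were also picked after the data were examined.

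Several genes of metallothioneins, small proteins that bind zinc and copper, were lower 1 day after detachment, which was not tested as a group. Of 10 genes, 8 were well above background on all arrays, and 6 of these were at least 2-fold lower in both lines. The 8 genes had a median difference of -3.14 in A549 and -2.41 in H441 at day 1 and -2.03 and -1.06 at day 7. MT1E had -3.52 and -2.55 at day 1 and MT2A -3.53 and -1.37, while MT1X had -2.89 and -2.54 at day 1 but 0.88 and 0.96 at day 7. Between FL detached and FL attached cells the genes did not move one way, with MT1E at 0.26 in A549-FL and -0.85 in H441-FL, MT1X at 2.23 and 0.53 and MT2A at -0.23 and -0.09. Probes of these paralogs can bind each other's transcripts, which was not tested.

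The gene sets of the parental lines were read in the FL sublines, on arrays they do not share. The 319 genes at least 2-fold higher at day 7 in both lines had medians of 0.98 in A549-FL and 0.72 in H441-FL between detached and attached cells. Of them, 79.3 percent were higher in both, against 32.7 percent of the 15470 genes bright enough for the day 7 count. The 184 lower genes had -0.75 and -0.41, with 72.3 percent lower in both, against 33.3 percent. The 272 genes higher at day 1 had 0.37 and 0.18, with 56.6 percent higher in both, against 32.4 percent of the 15487 genes of the day 1 count. The 394 lower genes had -0.19 and -0.13, with 48.5 percent lower in both, against 33.5 percent.

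Genes of small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA, had lower medians in detached cells. The median of 233 snoRNA genes was -0.30, -0.38 and -0.17 in A549 at day 1, at day 7 and in FL cells, and -0.13, -0.25 and -0.17 in H441. Each value lay below those of 10000 random lists of the array, a rank that a shift of the whole array does not alter. Attached FL cells were lower than attached parental cells too, by medians of -0.33 in A549 and -0.30 in H441. Chance differences of the attached array from the others of its population would give a mean difference as large as -0.24 in other arrangements, and the exact permutation p, two-sided over 36 arrangements, was 0.0278, the smallest they can give. The attached array was the highest of its population in every case when the genes were chosen, which alone gives this p, so chance stays open. RNA size selection during extraction was not tested either, nor was which transcripts these probes read after oligo(dT)-primed labelling.

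Probes with no gene name were also read in both lines. At day 1, 129 were at least 2-fold higher and 117 lower in both lines, where independent lines would give 31.8 and 32.2. In FL detached against parental attached cells 67 were higher and 196 lower, where independent lines would give 18.3 and 65.1.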
